A study of Mus musculus with 48 samples.

How the data were processed

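Mouse embryonic stem cells of 4 genotypes (wildtype, Zbtb11KO, Zfp131KO and a double knockout) were profiled by ChIP-seq for 9 targets, and the 48 samples were placed in 24 groups of 2 by target, genotype and culture, as the labels give them. All targets except HA were taken after 3 days without doxycycline. Every processed file covers a whole group or a comparison, so no value per region and library was available and no columns of other samples were present. Reads were aligned with Bowtie 1.0.1 to mm10, per the submitters' processing notes, which also name bedtools and DESeq2 1.28.1.

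The files were of 3 kinds. Binding events of NELF, CHD4, SIN3A, SETD1A and HA were called by the authors with MultiGPS against a control of 45.3 M reads, per the file headers, and hold the signal (reads assigned to an event, summed over replicates and not scaled for depth), a log2 fold over scaled control and a score that is the log2 of a p-value. The header of the wildtype NELF list names 1 signal replicate, and the others name 2. Domains of H3K4me3, H3K27ac, H3K27me3 and polymerase II were called by the authors with DomainFinder of SEED on pooled replicates at p under 0.01 with the ENCODE blacklist left out, per the file headers, and hold a read count and a p-value per domain. The authors' deposited DESeq2 tables hold a mean signal, a log2 fold change with its standard error, a Wald score, a p-value and a Benjamini-Hochberg adjusted p per region, with scaling not stated. Their regions join the wildtype and knockout lists and can overlap each other, and positive values mean higher in the knockout, as tested on regions listed in 1 genotype. From the values, the histone tables other than H3K4me3 in Zbtb11KO scale as reads per kb, and the NELF table runs well above the reads assigned to events.

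The planned count model needed counts per region and library, and the files hold none, so the planned fallback was used, and a region was called at an adjusted p under 0.05 of the authors' DESeq2 tables. The pair of NELF tables were identical and held the regions of the Zbtb11KO list, so NELF in Zfp131KO was compared from event lists alone. The event lists of CHD4 and SIN3A in Zfp131KO were identical and matched the CHD4 table, so SIN3A events in Zfp131KO were not used here. The double knockout was compared by lists of NELF and H3K4me3.

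Gene positions came from a RefSeq table of GRCm38.p6, the same assembly as mm10, which has 21883 protein-coding genes and gives neither strand nor start sites. A promoter was therefore a window of 1 kb around a gene end that held at least 33.3% of the H3K4me3 reads of the better end. Reads were summed over the H3K4me3 lists of all 4 genotypes, so knockout signal entered the choice. This gave 14563 genes with such an end, and both ends served for genes without one. The deleted genes were examined within 5 kb. Per gene the region with the highest mean signal was taken. Listed reads per promoter were compared for promoters with at least 50 wildtype reads; NELF reads were scaled by the total reads in the headers, and H3K4me3 reads were summed over stretches in which domains of all 4 genotypes were joined where they overlap, so that split and merged domains were compared over the same stretch. H3K4me3 sums were not scaled for depth, which the domain lists do not give.

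Events were compared within 500 bp, with 1000 circular shifts along chromosomes as background, and Wilson 95% intervals, which cover counting error only. Gene list medians were set against 10000 random lists of the same size matched on signal in 10 classes, and bound regions against random sets of unbound regions matched in the same way. The 16 lists were pluripotency, formative and primed, mesoderm and endoderm, neural, trophectoderm, primitive endoderm, fibroblast, two-cell-like, immediate early, p53 targets, Hox clusters, respiratory complex I, mitochondrial ribosome, cytosolic ribosome, housekeeping and the factors under study. Over 154 list medians in 11 tables, 64 lay outside the central 95% of random lists where 7.7 would by chance, and from listed reads 49 of 87 did. Paired shares at the 200 most significant events were compared with exact McNemar tests, and other shares with Fisher's exact test, two-sided. Segments were runs of at least 3 bins of 2 Mb with 20 or more regions whose SIN3A median deviated by at least 0.5. Shared changes in the tables were set against simulated unchanged groups that share the wildtype libraries.

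The tests, gene lists, most other settings tried and the rule for named genes were fixed before the data were examined. By that rule the text names up to 8 rises and 8 falls by log2 fold change for NELF and H3K4me3 and 4 and 4 for the other targets, among genes past the threshold with a mean signal at or above the median, up to 4 members of each list by adjusted p, the deleted genes, and the 10 most significant events of each HA list within 1 kb of a promoter, with tied scores ordered by reads. The comparison of the 200 most significant events with the genes named there, the largest changes in regions of 500 bp or more, the chromosome segments, the Y-linked genes beyond that rule and the genes given with listed reads were chosen after their values were seen. A few genes that the rule names are not reported here.

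The list percentile was tested on simulated data for H3K4me3 in Zfp131KO with 14265 promoters, where 7% of 100 unshifted lists of 25 genes and 100% of lists shifted by log2 1 lay outside or above the range. Calls after centring were tested on simulated data for NELF in Zbtb11KO over 70543 regions, where 2% of 200 regions raised by log2 1 and 58.5% of those raised by log2 2 were called. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered a stricter threshold, a minimum fold change, signal and width filters, centring, windows, random sets, regions in both lists, overlapping regions counted once, and chromosomes X and Y left out.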

Results

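ChIP-seq was measured in mouse embryonic stem cells for 9 targets in 48 samples, which fall into 24 groups of 2 libraries each. The targets were the pausing factor NELF, the chromatin regulators CHD4, SIN3A and SETD1A, RNA polymerase II phosphorylated at serine 5, the histone marks H3K4me3, H3K27ac and H3K27me3, and HA-tagged ZBTB11 or ZFP131. The genotypes were wildtype, Zbtb11KO, Zfp131KO and a double knockout, where each single knockout line carries an HA-tagged copy of the deleted factor, inducible by doxycycline, and the double line carries HA-tagged ZBTB11 and V5-tagged ZFP131. The wildtype cells are labelled as the iCre line. Because the labels name 1 line per genotype, an effect of a knockout cannot be told from a difference between lines. All targets except HA were measured after 3 days without doxycycline and without the 2 kinase inhibitors of the culture medium, and HA was measured with both present. Per the file headers, the event lists rest on 24.0 M (ZFP131) to 71.6 M (NELF, double knockout) reads. They name 2 replicates for each list except wildtype NELF, the reference of the listed NELF reads, where 1 is named. The share of reads in events ranged from 5.1% for NELF in the double knockout to 33.3% for SIN3A in wildtype. For NELF it was 2.7% and 8.0% in the 2 double knockout libraries, 8.4% and 11.7% in those of Zbtb11KO and 9.7% and 13.2% in those of Zfp131KO, so the pooled double knockout value hides a wide spread. The domain lists give no library totals. No file gives a value per region and library, so differences rest on the authors' DESeq2 tables. Their p-values measure the spread between libraries, which may be technical, since the labels do not say that replicates were separate cultures.

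The promoters of the deleted genes were examined first, although ChIP signal at a promoter does not check whether the coding sequence was deleted. Zbtb11 lies on chromosome 16 from 55971437 to 56008913 (mm10). Within 5 kb of its ends the H3K27me3 signal rose in Zbtb11KO by 3.06 (SE 0.61, adjusted p = 3.32e-05) on the log2 scale in the authors' deposited table. H3K4me3 near Zbtb11 rose in the same knockout, by 3.46 (SE 0.07) in the authors' deposited table, and in Zfp131KO by 0.26 (SE 0.10, adjusted p = 0.0418). H3K4me3 fold changes in Zbtb11KO ran wide, as given below, so the 3.46 was read by rank. Zfp131 lies on chromosome 13 from 119765186 to 119791477. In Zfp131KO the authors' deposited tables gave log2 fold changes of 0.24 (SE 0.11, adjusted p = 0.105) for H3K4me3, -0.33 (SE 0.31, adjusted p = 0.44) for H3K27ac and -0.02 (SE 0.23, adjusted p = 0.981) for SIN3A. Within 5 kb of the ends of Zbtb11 lay 4 ZBTB11 events with 3193 reads and 3 ZFP131 events with 332 reads. Within 1 kb there were 0 events of either factor.

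ZBTB11 and ZFP131, both zinc finger proteins, lay mainly within 500 bp of wildtype H3K4me3 domains, and most ZFP131 events lay beside a ZBTB11 event. By p-value 274 ZBTB11 and 65 ZFP131 events tied as most significant, and tied events were ordered by their reads. The first 10 ZBTB11 events within 1 kb of a gene end included Pemt, which makes phosphatidylcholine, the decapping factor gene Dcp1a, Ccdc57, the zinc transporter gene Slc39a13 and the ribosome assembly gene Wdr36. The others lay at Jrk, the mitochondrial ribosomal protein gene Mrps31, the protein kinase A subunit gene Prkacb, Commd2 and the syntaxin gene Stx16. The first ZFP131 events lay at Sphk2, a sphingosine kinase gene, between Rprd1b and Tti1, between Lias and the ribosomal protein gene Rpl9, at the signalosome gene Cops8 and at Aif1l and Nup214. The next lay at the ubiquinone synthesis gene Coq7, at Gm960 and Rce1, at Ndor1 and Tmem203, at the RNA polymerase III factor gene Bdp1 and at Prkrip1. Genes of the mitochondrial ribosome list carried ZBTB11 at 56 of 78 gene ends (71.8%) and cytosolic ribosome genes at 66 of 90 (73.3%), against 52.7% of all genes with H3K4me3 at an end and 35.5% of all protein-coding genes. Immediate early genes (16 of 24) and p53 targets (10 of 15) each carried it at 66.7%, pluripotency genes at 39.3%, neural genes at 34.8% and fibroblast genes at 8.33%. ZFP131 marked 24.4% of cytosolic ribosome genes, 29.2% of immediate early genes and 10.7% of pluripotency genes, against 15.2% of the genes with H3K4me3 and 10.2% of all protein-coding genes.

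Of the 3630 ZFP131 events, 67.7% (Wilson 95% interval 66.1 to 69.2) lay within 500 bp of a ZBTB11 event, against a mean of 0.798% after 1000 circular shifts. Of the 22432 ZBTB11 events 13.1% lay near a ZFP131 event. The p of each shift test was 0.001, the smallest that 1000 shifts can give. Circular shifts move events away from promoters and H3K4me3 domains, so they cannot part shared binding from a common preference for such sites. Among the 48716 wildtype H3K4me3 domains, 12339 carried ZBTB11, 2471 carried ZFP131 and 1947 carried both, with an odds ratio of 12.8. ZBTB11 was thus also more frequent at domains with ZFP131 than at other domains. Domains were not matched on signal in this comparison. Promoter windows held 47.6% of the ZBTB11 and 71.5% of the ZFP131 events, and wildtype H3K4me3 domains 75.3% and 89.3%. Wildtype NELF events lay near 72.1% of ZBTB11 and 88.5% of ZFP131 events, SIN3A near 72.2% and 89.4%, and SETD1A, a catalytic subunit of an H3K4 methyltransferase, near 53.8% and 80.2%. CHD4, the ATPase of the NuRD complex, lay near 13.4% and 20.7%, and domains of polymerase II phosphorylated at serine 5 near 66.3% and 85.6%. The p-values and reads of these lists are the authors' own and were used only within a list.

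Where each factor bound most strongly, a minority of active promoters gained the repressive mark H3K27me3 in the knockout of that factor, and far fewer did in the other knockout. In Zbtb11KO the gains named here lay at the promoter shared by Mrpl13 and the Mdm2-binding protein gene Mtbp, at Taco1, a translational activator of cytochrome c oxidase, at Ccdc57, at the SNARE gene Vti1a with Zdhhc6, at Acbd6 and the mitochondrial ribosomal gene Mrps18c. In Zfp131KO they lay at other genes, the RNA helicase gene Ddx51 with the ribosome biogenesis gene Noc4l, the nuclear pore gene Nup214, Scfd2, the ribosomal RNA processing gene Rrp1b and the decapping exonuclease gene Dxo. The authors' deposited table gave H3K27me3 log2 fold changes in Zbtb11KO of 4.64 (SE 0.57, adjusted p = 6.94e-13) for Mrpl13, 3.42 (SE 0.42) for Taco1 and 3.23 (SE 0.44) for Ccdc57. It gave 3.26 (SE 0.45) for Vti1a, 3.49 (SE 0.49) for Acbd6 and 3.51 (SE 0.45) for Mrps18c. In Zfp131KO the authors' deposited table gave 3.84 (SE 0.43, adjusted p = 2.59e-15) for Ddx51, 3.90 (SE 0.48) for Nup214, 3.90 (SE 0.49) for Scfd2, 3.84 (SE 0.50) for Rrp1b and 4.04 (SE 0.65) for Dxo.

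The 200 ZBTB11 events taken as most significant were those with the most reads among the 274 tied, and the 200 of ZFP131 included all 65 tied. Among the 200 most significant ZBTB11 events, none lay within 500 bp of an H3K27me3 domain in wildtype, against 40 (20.0%, Wilson 95% interval 15.0 to 26.1) in Zbtb11KO and 1 in Zfp131KO (exact McNemar p = 1.82e-12 against wildtype and 3.82e-11 against the other knockout, two-sided). Among the 200 most significant ZFP131 events, 1 lay near a domain in wildtype and 4 in Zbtb11KO, against 49 (24.5%, 19.1 to 30.9) in Zfp131KO (exact McNemar p = 7.11e-15 and 6.82e-13). H3K27ac domains, which mark active promoters, remained near 159 of these ZBTB11 events (79.5%) in Zbtb11KO, all of them among the 196 with a domain in wildtype, and near 163 of the ZFP131 events (81.5%) in Zfp131KO, all among the 197 of wildtype. H3K27ac fell, by the authors' adjusted p, at 36 of the 40 ZBTB11 events that gained an H3K27me3 domain (90.0%) and at 41 of the other 160 (25.6%), with a Fisher's exact p of 5.36e-14. It fell at 43 of the 48 ZFP131 events that gained a domain (89.6%) and at 55 of the other 152 (36.2%), with a Fisher's exact p of 3.47e-11. The other events shifted less, from 19.8% of ZBTB11 events near an H3K27me3 domain in wildtype to 22.3% in Zbtb11KO and 21.7% in Zfp131KO, and from 17.5% of ZFP131 events to 20.1% and 24.9%. Events are not independent replicates, and the choice of the 200 most significant events was made after the tables had been seen.

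**Figure D1:**
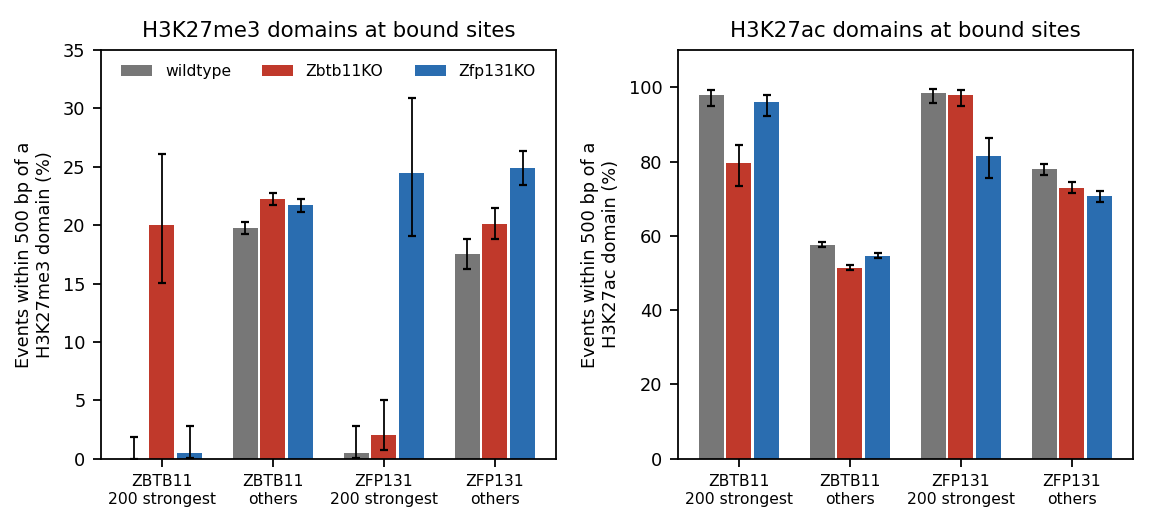
Share of binding events (percent) within 500 bp of an H3K27me3 domain (left) or an H3K27ac domain (right) in wildtype, Zbtb11KO and Zfp131KO, for the 200 most significant and the other events of each factor, with Wilson 95% intervals that cover counting error only. The H3K27me3 bar reaches 20.0% for the ZBTB11 events in Zbtb11KO and 24.5% for the ZFP131 events in Zfp131KO, against 0.5% or less in wildtype.

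NELF, which holds polymerase II in the paused state near promoters, was lower at nearly all promoters in each knockout and lowest in the double knockout, and pluripotency and neural genes lay lowest in Zbtb11KO. Fgf4, a growth factor gene of pluripotent cells, Nr0b1, Zfp42 and the core factor gene Sox2 fell in Zbtb11KO, with log2 fold changes in the authors' deposited table of -2.19 (SE 0.35, adjusted p = 2.88e-07), -2.06 (SE 0.34), -2.00 (SE 0.35) and -1.93 (SE 0.36). Of the 25 pluripotency genes with a region, 20 fell, and likewise 20 adjusted over the list alone, with a median of -1.45 at percentile 0 of 10000 random gene lists matched on signal. Of 19 neural genes 12 fell, 13 adjusted over the list alone. Among them were the tubulin gene Tubb3 and the Notch target Hes5, at -2.18 (SE 0.31) and -2.58 (SE 0.45) in the authors' deposited table. Primitive endoderm genes lay highest, with a median of -0.44 at percentile 100. The authors' deposited table gave rises for the endoderm factor genes Gata4 at 1.94 (SE 0.74, adjusted p = 0.0253) and Sox7 at 0.90 (SE 0.39, adjusted p = 0.0423), which did not pass adjusted over the list alone. The p53 targets (median -0.47, percentile 100), the Hox clusters (-0.73, percentile 99.8) and cytosolic ribosome genes (-0.74, percentile 99.8) also lay above matched genes, with 2 of 14, 8 of 34 and 43 of 80 members called lower, and 0, 6 and 44 adjusted over the list alone. Of 12 formative and primed genes 9 fell, and of 11 trophectoderm genes 2. Of 12 housekeeping genes 7 fell, and of 13 genes of the factors under study 11, with each of these medians inside the central 95% of random lists. Among all promoters with a region 55.3% were called lower, so counts such as 7 of 12 and 43 of 80 lie near the general share.

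The largest NELF falls in Zbtb11KO were at Padi3, Zfp11, the AKT coactivator gene Tcl1, the myelin gene Mobp, the calcium channel subunit gene Cacng5, Ldlrad4, the lysosomal regulator gene Tfeb and the meiotic kinase gene Aurkc. They ranged from -2.83 for Aurkc to -3.13 for Padi3 in the authors' deposited table. The named rises included the imprinted genes Plagl1, Peg10 and Sgce, at 1.30 (SE 0.37, adjusted p = 0.00341), 0.90 (SE 0.39, adjusted p = 0.0465) and 0.90 (SE 0.39, adjusted p = 0.0465) in the authors' deposited table, beside Dglucy, Cpne2, Sox7 and the X-linked Pin4. Of all 70551 regions, 34548 fell and 112 rose in the authors' deposited table. The share of rises was 0.323% and became 53.8% when fold changes were centred on the median of all regions (-1.04), with 396 calls left. Without a reference added to the libraries, a fall at all sites cannot be told from lower enrichment, and the share of reads in events moved in the same direction, from 23.1% in wildtype to 9.8%.

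Reads assigned to NELF events, scaled by the total reads in the file headers, allowed a description of all 3 knockout genotypes without a test. Of 12796 promoters with at least 50 wildtype reads, 72.7% were still listed in Zbtb11KO, 74.5% in Zfp131KO and 49.4% in the double knockout. The median log2 ratios to wildtype were -0.90, -0.72 and -1.75. Reads of single genes are given as listed, not scaled, from totals of 60.5 M in wildtype, 51.1 M in Zbtb11KO, 61.5 M in Zfp131KO and 71.6 M in the double knockout. Fgf4 had 1403 reads in wildtype and 261 in Zbtb11KO, and Nanog 779 and 170. Neither had an event in the lists of Zfp131KO and the double knockout. Sox2 had 1156 reads in wildtype and 325 in Zfp131KO, with no event in Zbtb11KO or the double knockout. List medians cover only members still listed in the knockout, a filter that the change itself affects, and rest on 17, 18 and 10 of 24 pluripotency genes and 7, 9 and 3 of 18 neural genes in Zbtb11KO, Zfp131KO and the double knockout. Relative to all promoters, the pluripotency list lay at -0.64 in Zbtb11KO and -1.14 in the double knockout, and at -0.22 in Zfp131KO, inside the range of random lists (percentile 6.25). The neural list lay at -1.30 in Zbtb11KO and -1.01 in Zfp131KO, and at -0.29 in the double knockout (percentile 14.8), inside the range. The p53 targets lay higher in every genotype, at 0.65 in Zbtb11KO, 0.85 in Zfp131KO and 0.76 in the double knockout. Mdm2 went from 1668 wildtype reads to 1346, 2560 and 1475. Primitive endoderm genes lay at 0.64 in Zbtb11KO, 0.46 in Zfp131KO and 0.32 in the double knockout (percentile 94.0), and cytosolic ribosome genes at 0.43, 0.40 and 0.49. Formative and primed genes lay at -0.29 in Zbtb11KO (percentile 3.22), -0.57 in Zfp131KO and -0.92 in the double knockout, where 4 of 12 were still listed. Of the wildtype NELF events 40.7%, 43.4% and 26.1% had an event within 500 bp in Zbtb11KO, Zfp131KO and the double knockout, while 96.9%, 94.9% and 96.5% of the knockout events had a wildtype event.

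**Figure D2:**
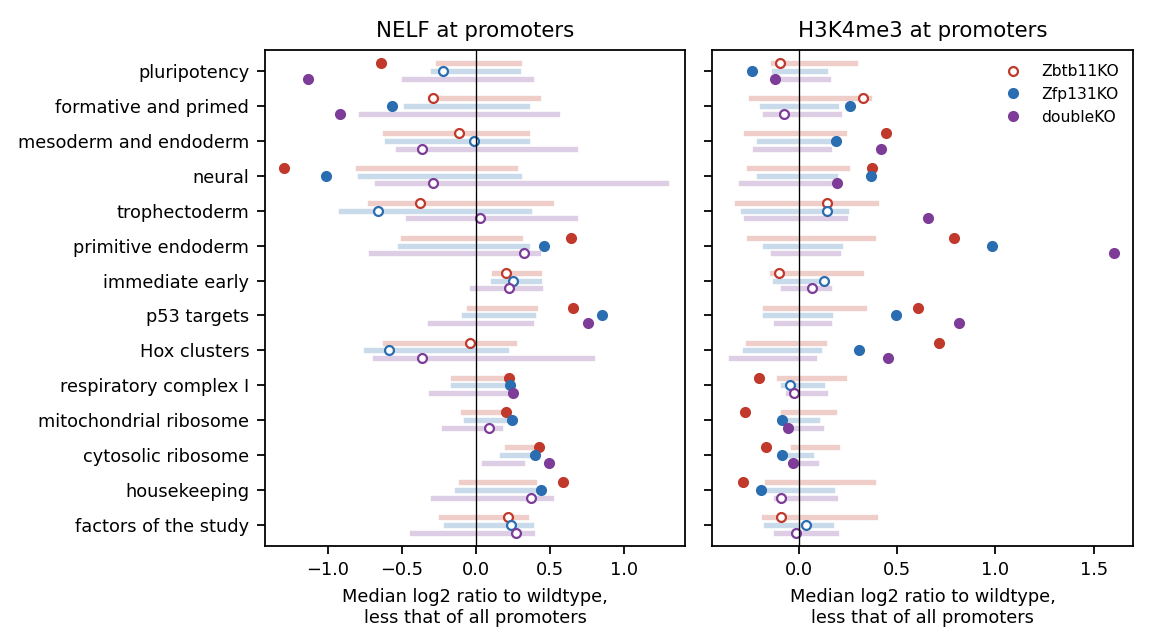
Median log2 ratio to wildtype of NELF (left) and H3K4me3 (right) listed reads at promoters of each gene list, less the median of all promoters, in Zbtb11KO, Zfp131KO and the double knockout. Bars span the central 95% of 10000 random lists, and filled points lie outside them, as for primitive endoderm H3K4me3 in the double knockout at 1.60.

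H3K4me3, the mark of active and poised promoters, was higher at genes of primitive endoderm and at p53 targets in Zfp131KO by table and by listed reads, while Zbtb11KO and the double knockout stood out by listed reads alone. In Zfp131KO the endoderm factor genes Sox17, Gata4 and Gata6 and the laminin gene Lamb1 rose, at 1.44 (SE 0.16, adjusted p = 7.66e-16), 3.07 (SE 0.62), 1.56 (SE 0.34) and 1.61 (SE 0.38) on the log2 scale in the authors' deposited table. Of 14 primitive endoderm genes 7 rose, 8 adjusted over the list alone, with a median of 1.16 at percentile 100. Of 15 p53 targets 11 rose, 12 adjusted over the list alone. Among them were the cell cycle inhibitor gene Cdkn1a, the cell death gene Bbc3, Phlda3 and Zmat3, at 1.18 (SE 0.14), 0.87 (SE 0.10), 1.02 (SE 0.11) and 0.88 (SE 0.10) in the authors' deposited table. Hox genes rose at 10 of 37 and mesoderm and endoderm genes at 10 of 24, with list medians at percentiles 100 and 99.6. Among all promoters 33.5% were called as rises. Hox genes, and the neural genes below, were therefore not called more often than promoters in general, and they stand out by their medians alone. Hoxc13 was at 1.99 (SE 0.13) and Hhex at 0.53 (SE 0.09) in the authors' deposited table. Neural genes rose at 5 of 22, 4 adjusted over the list alone, led by Neurod1 at 1.64 (SE 0.25) in the authors' deposited table, while the pluripotency median (0.01) lay at percentile 0.21. Mitochondrial ribosome genes rose at 30 of 73 and fell at 4, and cytosolic ribosome genes rose at 19 of 83 and fell at 3, yet both medians (0.20 and 0.20) lay below matched genes, at percentiles 0.58 and 0.16. Trophectoderm genes rose at 2 of 11, fibroblast genes at 1 of 7, housekeeping genes at 2 of 12, formative and primed genes at 3 of 13 and the factors under study at 7 of 13. Of these 5 lists only housekeeping, at percentile 1.43, left the central 95% of random lists.

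In Zbtb11KO, mesoderm and endoderm, Hox and neural genes were again higher than matched genes, and genes of mitochondria and ribosomes lower. By listed reads, not scaled for depth, the median log2 ratios of mesoderm and endoderm, Hox and neural genes were 0.02, 0.29 and -0.05. Trophectoderm genes rose at 2 and fell at 2 of 11 (percentile 60.6). Formative and primed genes rose at 9 and fell at 2 of 13 (percentile 96.2), inside the range. Of 24 mesoderm and endoderm genes 14 rose, 15 adjusted over the list alone, and 2 fell, with Eomes at 2.68 (SE 0.10), Isl1 at 2.82 (SE 0.12) and Hhex at 2.01 (SE 0.09) in the authors' deposited table. The listed reads of Eomes, Isl1 and Hhex, not scaled for depth, moved far less. They went from 2632 in wildtype to 3340 in Zbtb11KO at Eomes, 1516 to 2068 at Isl1 and 4171 to 4997 at Hhex. Hox genes rose at 19 of 37 and fell at 1, led by Hoxd8 at 3.65 (SE 0.19), and neural genes rose at 13 of 22 and fell at 1, led by Ncam1 at 1.83 (SE 0.09) in the authors' deposited table, although the listed reads of Ncam1, not scaled for depth, were 4468 in wildtype and 3845 in Zbtb11KO. Mitochondrial ribosome genes fell at 41 of 74, 44 adjusted over the list alone (median -0.59, percentile 0), and rose at 12. Complex I genes fell at 23 of 44, 26 adjusted over the list alone (-0.47, percentile 0), and rose at 7, and cytosolic ribosome genes fell at 37 of 84 (-0.24, percentile 0) and rose at 15. The complex I gene Ndufc2 fell, at -3.16 (SE 0.26), as did the assembly factor gene Ndufaf1, at -2.64 (SE 0.27), and Mrps31, one of the most strongly bound genes, at -2.39 (SE 0.20) in the authors' deposited table. Of 15 p53 targets 10 rose and of 13 primitive endoderm genes 8, with list medians at percentiles 16.7 and 91.4, inside the range of matched genes. Pluripotency genes rose at 10 and fell at 9 of 26 (percentile 1.94), and immediate early genes rose at 8 and fell at 8 of 23 (percentile 1.87). Housekeeping genes fell at 8 of 12 and rose at 2 (percentile 0.07), and fibroblast genes rose at 2 of 7. No member of the two-cell-like list had a region at a promoter in any of the tables. The largest falls among the named genes were at the Y-linked genes Eif2s3y, Uty and Ddx3y, at -7.62, -6.15 and -4.94 in the authors' deposited table, and at Acsf3. Copy number of Y was not measured, so the Y-linked falls may belong to the line. The largest rises included Gm11543, Pdgfrb, the small Maf gene Mafg with the sirtuin gene Sirt7, Lrrc2, the RNA-binding protein gene Qk, the X-linked Nhsl2, the mitochondrial coactivator gene Ppargc1a and Nedd1. They ran from 4.30 for Nedd1 to 5.56 for Gm11543 in the authors' deposited table, values that were read by rank, as given below. In Zfp131KO the largest rises included Mmrn2 with Sncg, at 4.44 (SE 0.54, adjusted p = 3.53e-14), and Plcd4 with Usp37, at 3.38 (SE 0.43, adjusted p = 4.76e-13) in the authors' deposited table. The largest falls in regions of 500 bp or more were at the histone gene H3f3b, Zfp72 and Tbl3, at -6.49 (SE 0.90), -3.02 (SE 0.22) and -2.96 (SE 0.17) in the authors' deposited table.

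The authors' deposited tables called 10822 rises and 6503 falls of 62288 H3K4me3 regions in Zbtb11KO, where 12071 regions had no adjusted p, and 9074 rises and 6867 falls of 60238 in Zfp131KO. Of the Zfp131KO falls 5481 lay in regions listed in wildtype alone, and regions in both lists gave 6067 rises and 1351 falls. At promoters there were 6037 rises and 3479 falls in Zbtb11KO and 4773 and 591 in Zfp131KO. By listed reads, not scaled for depth, 77.7% and 62.9% of promoters were lower in Zbtb11KO and Zfp131KO, so this balance depends on the scaling. Centring on the median of all regions moved the share of rises from 62.5% to 72.9% in Zbtb11KO. Fold changes in the Zbtb11KO table ran wider than those from the listed reads, with an SD over promoters of 1.33 against 0.63. Its values for single genes such as Mafg, listed with 2765 reads in wildtype and 3827 in Zbtb11KO, were therefore read by rank (Spearman 0.855 across promoters).

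The listed H3K4me3 reads, summed over the same joined stretches in all genotypes and not scaled for depth, extended these groups to the double knockout. Gata6 had 1221 reads over 2715 bp in wildtype, 2891 over 4685 bp in Zbtb11KO, 3431 over 5271 bp in Zfp131KO and 11275 over 8398 bp in the double knockout. Pdgfra, a receptor gene of primitive endoderm, went from 1547 reads over 2607 bp in wildtype to 10194 over 6251 bp in the double knockout, and Lamb1 from 1378 over 2010 bp to 10636 over 6945 bp. The primitive endoderm list lay above all promoters by 0.79 in Zbtb11KO, 0.98 in Zfp131KO and 1.60 in the double knockout, and the p53 targets by 0.61, 0.49 and 0.81. Trophectoderm genes stood apart in the double knockout at 0.66, and Hox genes lay at 0.71, 0.31 and 0.45. Mdm2, which encodes the ubiquitin ligase of p53, had 6518 reads over 3229 bp in wildtype and 21752 over 9761 bp in the double knockout, and Cdkn1a 5166 over 2861 bp and 19157 over 7108 bp. At the strongly bound Mrps31 the reads went from 3090 over 1839 bp in wildtype to 558 over 987 bp in Zbtb11KO, 2437 over 1368 bp in Zfp131KO and 1654 over 1368 bp in the double knockout. Ndufc2 had 2337 reads over 1132 bp in wildtype, 288 over 659 bp in Zbtb11KO and 656 over 794 bp in the double knockout. All promoters together had median log2 ratios of -0.42, -0.10 and 0.72. The 13641 promoters listed in the double knockout had median covered lengths of 1726 bp in wildtype and 1868 bp in the double knockout and 1.23 and 1.90 reads per bp. Of the wildtype domains 64.3%, 65.6% and 74.2% overlapped a domain in Zbtb11KO, Zfp131KO and the double knockout, and of the 19332 domains of 500 bp or more 98.8%, 98.9% and 99.3%.

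H3K27ac fell at 4 of the 7 primitive endoderm genes with a region in each knockout and rose at p53 targets in Zfp131KO. The type IV collagen genes Col4a1 and Col4a2 and the laminin gene Lama1 fell in Zbtb11KO, at -2.17 (SE 0.32), -1.63 (SE 0.35) and -1.28 (SE 0.38), and in Zfp131KO, at -2.69 (SE 0.45), -1.34 (SE 0.32) and -1.25 (SE 0.32) in the authors' deposited tables. With Sox7, which with these genes was measured partly in regions as short as 39 bp, 4 of 7 primitive endoderm genes fell in each knockout (medians -1.28 and -1.25, percentiles 0.19 and 0.59). Col4a1 and Col4a2 had the same H3K4me3 stretch at their promoters, so they are not fully separate members. Its listed H3K4me3 reads, not scaled for depth, went up, from 3019 in wildtype to 4708 in Zbtb11KO and 5294 in Zfp131KO. Of 14 p53 targets 7 rose in Zfp131KO, 8 adjusted over the list alone. Bbc3, Zmat3 and Ccng1 were at 0.60 (SE 0.16), 0.77 (SE 0.26) and 0.65 (SE 0.22) in the authors' deposited table. Lin28a, an RNA-binding protein gene of pluripotent cells, and the Nodal antagonist gene Lefty1 fell in both. Lin28a was at -2.93 (SE 0.38, adjusted p = 1.47e-11) in Zbtb11KO and -2.31 (SE 0.33, adjusted p = 8.93e-10) in Zfp131KO and Lefty1 at -2.61 (SE 0.41) and -1.52 (SE 0.33) in the authors' deposited tables. The pluripotency list as a whole lay above matched genes (medians 0.33 and 0.34, percentile 100 in each), with 8 rises and 3 falls of 24 in Zbtb11KO and 4 and 3 in Zfp131KO. Immediate early genes fell at 9 of 22 in Zbtb11KO, 10 adjusted over the list alone, and rose at 2, with Fosb at -1.68 (SE 0.29) and Junb at -1.18 (SE 0.31) in the authors' deposited table (list percentile 0). At the strongly bound Ccdc57, Wdr36 and Mrps31 it fell in Zbtb11KO, at -2.60 (SE 0.52), -2.06 (SE 0.37) and -1.37 (SE 0.37), and at Coq7 and Cops8 in Zfp131KO, at -1.98 (SE 0.31) and -1.87 (SE 0.47) in the authors' deposited tables. St8sia1, a sialyltransferase gene, rose in both, at 2.45 (SE 0.35) and 2.37 (SE 0.32) in the authors' deposited tables.

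The authors' deposited tables called 9923 rises and 7996 falls of 68017 H3K27ac regions in Zbtb11KO and 10879 and 9870 of 69018 in Zfp131KO. Most calls lay in short regions listed in 1 genotype. Regions in the lists of both genotypes gave 1571 rises and 795 falls in Zbtb11KO and 2351 and 965 in Zfp131KO. At promoters, with the region of highest signal per gene, falls outnumbered rises, with 375 rises and 1030.0 falls in Zbtb11KO and 429 and 1144 in Zfp131KO. Within 500 bp of an event of either factor the median log2 fold change was -0.11 in Zbtb11KO and -0.12 in Zfp131KO, below random sets of unbound regions (percentile 0), but above them when those sets were drawn from unbound promoter regions.

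H3K27me3 fell at developmental genes in Zfp131KO, most widely at the Hox clusters. Listed H3K27me3 domains as a whole held 0.299 reads per bp over 12.5 Mb in Zfp131KO, against 0.379 over 17.0 Mb in wildtype. Whether lower enrichment of the libraries contributes to these falls was not tested. Of 38 Hox genes 18 fell, 28 adjusted over the list alone, with Hoxc13 at -1.82 (SE 0.43), Hoxc6 at -1.26 (SE 0.34) and Hoxd3 at -1.17 (SE 0.34) in the authors' deposited table (list median -0.87, percentile 0). Neighbouring Hox genes are not fully separate members. Hoxb7 and Hoxb8, for example, had the same listed H3K4me3 reads in each genotype (1395 in wildtype). Random lists drew genes singly, so Hox counts and percentiles for every target do not allow for this. Neural genes fell at 8 of 21, 11 adjusted over the list alone, and mesoderm and endoderm genes at 7 of 24, 12 adjusted over the list alone. Neurod1, Nkx2-2 and Pax3 were at -1.94 (SE 0.39), -1.05 (SE 0.31) and -0.98 (SE 0.33), and Meis2 and Foxa2 at -1.54 (SE 0.42) and -0.95 (SE 0.32) in the authors' deposited table. The trophectoderm genes Cdx2, Eomes and Esx1 fell (3 of 13), with Cdx2 at -0.94 (SE 0.31) in the authors' deposited table. In Zbtb11KO the Hox median was -0.50 (percentile 0) with 1 of 38 members called lower, Hoxa2 at -0.98 (SE 0.33, adjusted p = 0.0274) in the authors' deposited table, and none adjusted over the list alone. Pluripotency genes fell at 3 of 12, among them Tbx3 at -2.66 (SE 0.48) in the authors' deposited table. The mitochondrial ribosome genes Mrpl13, Mrps18c and Mrpl53 rose (3 of 6, percentile 100), with Mrpl53 at 2.39 (SE 0.48), and so did the complex I genes Ndufc2 and Ndufa13 (2 of 4), at 2.48 (SE 0.38) and 1.24 (SE 0.32) in the authors' deposited table. Formative and primed genes rose at 3 of 11 in Zbtb11KO, and fibroblast genes had medians of -0.22 and -0.56 in Zbtb11KO and Zfp131KO over 7 members, inside the central 95% of random lists. Among regions of 500 bp or more the largest rises were at Mrpl13, Zfp11, Slc4a1ap with Supt7l and Adat2 with Pex3 in Zbtb11KO, from 4.16 to 4.64 in the authors' deposited table. In Zfp131KO they were at Clptm1l, Dxo, the RNA-editing gene Adar and Ctu2, from 3.95 to 4.06, while Plk2 fell in both, at -2.05 (SE 0.35) and -3.39 (SE 0.52) in the authors' deposited tables.

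Of 79775 H3K27me3 regions in Zbtb11KO the authors' deposited table called 7255 rises and 3853 falls, and of 73570 in Zfp131KO 8590 and 4545. The median region was 65 bp and 66 bp long. Regions listed in both genotypes gave 78 rises and 255 falls in Zbtb11KO and 119 and 847 in Zfp131KO, so the direction of the count turned when regions listed in 1 genotype were left out. At promoters there were 381 rises and 207 falls in Zbtb11KO and 603 and 421 in Zfp131KO. Within 500 bp of the 200 most significant ZBTB11 events 43 of 53 regions rose in Zbtb11KO (median 2.79), and 64 of 78 near the ZFP131 events rose in Zfp131KO (median 2.97). Regions near the other events had medians of -0.13 and -0.15. At most 1 of each 200 events lay near a wildtype domain, so nearly all of these regions entered through the knockout list. Regions in that list alone gave 7174 rises and 3 falls in Zbtb11KO and 8464 and 1 in Zfp131KO. The selection thus set the direction, and these medians add no support to the domain counts.

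CHD4 changed at few promoters. The largest rises in Zbtb11KO were at Ogt, the gene of the O-GlcNAc transferase, the Polycomb accessory gene Aebp2, the WNT regulator gene Amer1 and Usp48, at 2.09 (SE 0.38, adjusted p = 9.61e-06), 1.86 (SE 0.44), 1.74 (SE 0.37) and 1.65 (SE 0.43) in the authors' deposited table. The largest fall was at Ino80b, a subunit gene of the INO80 remodeller, at -1.75 (SE 0.41, adjusted p = 8.13e-04) in the authors' deposited table. In Zfp131KO Trim36, Mib2, the ubiquitin ligase gene Rnf125 and Tm7sf3 rose, at 2.18 (SE 0.42), 1.60 (SE 0.32), 1.43 (SE 0.19) and 1.41 (SE 0.30) in the authors' deposited table. Falls in Zfp131KO included Serf1, Lexm and Slc35g2, at -1.53 (SE 0.37), -1.46 (SE 0.40) and -1.45 (SE 0.39) in the authors' deposited table. Mitochondrial ribosome genes had a median of -0.53 over 9 members in Zbtb11KO (percentile 0.06). Primitive endoderm, trophectoderm, neural and Hox genes had medians of 0.50, 0.57, 0.78 and 0.47 above the central 95% of random lists, without a call for single members. These medians rest on 7, 5, 3 and 6 genes with a region. In Zfp131KO the Hox list lay outside the range again (percentile 98.5). Primitive endoderm, trophectoderm and neural lists lay inside it (80.9, 66.4 and 91.0). In all, 969 regions rose and 291 fell of 10326 in Zbtb11KO, and 1314 rose and 1319 fell of 16322 in Zfp131KO. At promoters 53 rose and 17 fell of 2983 in Zbtb11KO, while in Zfp131KO 26 rose and 222 fell of 3701, with a median of -0.28. Ogt and Amer1 lie in a part of chromosome X that held 57 of the 71 CHD4 rises on that chromosome.

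SIN3A, the scaffold of a histone deacetylase complex, fell at some immediate early genes and few pluripotency and neural genes and rose at some p53 targets. Pluripotency genes fell at 1 of 25 in Zbtb11KO (median -0.13, percentile 0.13), and 3 fell and 1 rose of 24 in Zfp131KO (-0.04, percentile 0.98). Lin28a fell in both knockouts, at -1.14 (SE 0.20, adjusted p = 9.68e-06) and -1.10 (SE 0.20, adjusted p = 1.93e-05), and Nanog in Zfp131KO, at -0.67 (SE 0.17, adjusted p = 0.00526) in the authors' deposited tables. Immediate early genes fell at 4 of 24 and rose at 1 in Zbtb11KO, 5 and 1 adjusted over the list alone. They fell at 3 of 23 and rose at 1 in Zfp131KO, 5 and 3 adjusted over the list alone, with percentile 0.04 in each knockout. Jund was at -0.55 (SE 0.15) and -0.73 (SE 0.15) in the authors' deposited tables. Of 14 p53 targets 4 rose in Zfp131KO, 7 adjusted over the list alone, with the cell adhesion gene Perp at 1.07 (SE 0.20) and Phlda3 at 0.93 (SE 0.18) in the authors' deposited table. The list lay at percentile 99.0. In Zbtb11KO 2 of 14 p53 targets rose, 4 adjusted over the list alone, with the median inside the range (percentile 94.0). Neural genes fell at 3 of 21 in Zbtb11KO (percentile 1.2) and at 1 of 18 in Zfp131KO (percentile 0.84). Cytosolic ribosome genes rose at 7 of 81 in Zbtb11KO, 12 adjusted over the list alone, led by the X-linked Rps4x at 1.31 (SE 0.25) in the authors' deposited table (list percentile 99.9). The largest rises in Zbtb11KO, at 8030474K03Rik with Gm4779, Gspt2, Uprt and Phka1, were all on chromosome X, from 1.75 to 2.29 in the authors' deposited table. The largest falls were at Wdr31, Wdr83, Ttc26 and Man2b1, from -2.11 to -2.30 in the authors' deposited table. In Zfp131KO, Zfp365, the stress response gene Ddit4 and Tysnd1 on chromosome 10 and the epoxide hydrolase gene Ephx1 rose most, from 1.49 to 1.70 in the authors' deposited table. Tbl3, Haus5, the Notch ligand gene Dll4 and Rmdn3 fell most, from -1.46 to -1.70 in the authors' deposited table. At promoters 769 rose and 315 fell in Zbtb11KO and 723 and 195 in Zfp131KO. In all, 4327 regions rose and 4063 fell of 125643 in Zbtb11KO and 2045 and 1952 of 68634 in Zfp131KO, where part of the regions came from an event list not used here.

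Part of chromosome X in Zbtb11KO, from 92 to 108 Mb (mm10), and part of chromosome 10, from 58 to 64 Mb in Zbtb11KO and to 68 Mb in Zfp131KO, carried higher values of every target with a table. On the X segment SIN3A had a median of 1.08 in Zbtb11KO against 0.06 on the rest of X, and 341 of the 416 SIN3A rises on X lay there. In Zbtb11KO the segment lay above the rest of X by 0.85 for NELF, 0.91 for H3K4me3, 1.23 for H3K27ac, 1.59 for H3K27me3 and 0.77 for CHD4. In Zfp131KO the differences were -0.19 for H3K4me3, -0.18 for H3K27ac, 0.06 for H3K27me3, -0.53 for CHD4 and 0.02 for SIN3A. On chromosome 10 from 58 to 64 Mb, which holds Ddit4 and Tysnd1, the difference from the rest of the chromosome was 0.70 for SIN3A in Zbtb11KO and 0.67 in Zfp131KO, and 0.93 and 1.03 for H3K27ac. Another segment, on chromosome 18 from 4 to 12 Mb in Zbtb11KO, was weaker and not shared by all targets. There the difference was 0.47 for SIN3A, 0.32 for NELF, 0.31 for H3K4me3, 0.36 for H3K27ac, 0.33 for CHD4 and -0.03 for H3K27me3. The segments were set on SIN3A in bins of 2 Mb after the values had been seen. Whether extra copies account for the chromosome 10 segment, and so for the rises at Ddit4, Tysnd1 and Zfp365, was not tested.

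**Figure D3:**
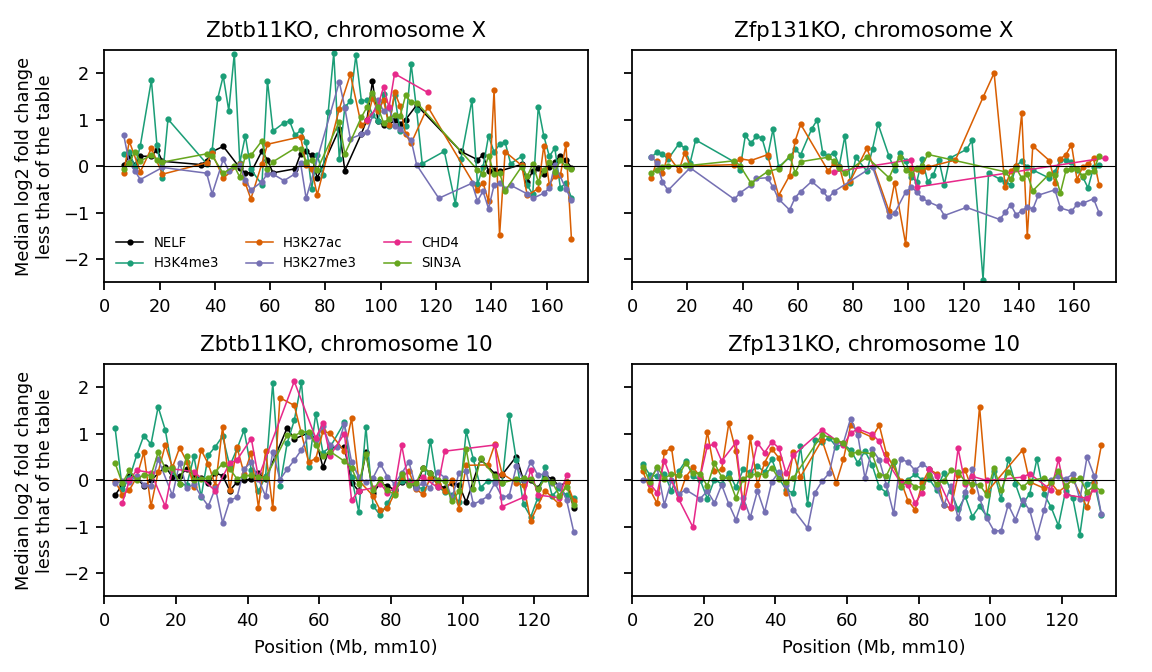
Median log2 fold change of table regions in 2 Mb bins along chromosomes X and 10 (mm10), less the median of the table, for each target in Zbtb11KO and Zfp131KO. The targets rise together on X from 92 to 108 Mb in Zbtb11KO and on 10 from 58 to 64 Mb in both knockouts.

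Fold changes of the single knockouts were compared for each target over shared regions, where common wildtype libraries give a positive correlation without any effect. CHD4 had a Pearson correlation of 0.805 (0.489 simulated without effect), SIN3A 0.641 (0.494), H3K27ac 0.638 (0.338), H3K27me3 0.553 (0.399) and H3K4me3 0.366 (0.392). The CHD4 value depended on the regions used. Over the 2128 CHD4 regions listed in wildtype and each single knockout it was 0.493, near the 0.489 simulated without effect over all shared regions. With regions limited in this way, SIN3A had 0.627, H3K27ac 0.728, H3K27me3 0.616 and H3K4me3 0.391. Over all shared regions the covariances were 0.496 (0.0935 simulated) for CHD4, 0.135 (0.0448) for SIN3A, 0.654 (0.133) for H3K27ac, 0.286 (0.138) for H3K27me3 and 0.892 (0.341) for H3K4me3. Rises called in both knockouts numbered 1526 for H3K27ac, 3251 for H3K4me3, 130.0 for H3K27me3, 248 for CHD4 and 495 for SIN3A, and falls 4052, 811, 1080.0, 251 and 880.0. Independent calls would share 114, 1049, 1.77, 17.5 and 49.0 rises in the same order. They would share 1727, 875, 418, 42.0 and 85.4 falls. The 811 shared H3K4me3 falls thus lay below the value for independent calls, and the other counts above theirs. For NELF the listed reads at 8734 promoters gave a correlation of 0.656, and 75.7% of promoters lay on the same side of both medians, without a value for no effect that holds the spread between libraries. The 2 wildtype libraries could not be split, so part of each correlation and overlap may come from the shared controls, and regions are not independent replicates.

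NELF and H3K4me3 changes in Zbtb11KO were at most weakly related in size across 12834 promoters, with a Pearson correlation of -0.01 and a Spearman correlation of -0.05. Promoters where NELF fell included 3527 of the 5773 where H3K4me3 rose, with an odds ratio of 1.46 and a two-sided Fisher's exact p of 2.34e-26, and 1813 of the 3296 where it fell, with an odds ratio of 0.95 and p = 0.207. Promoters are not independent replicates, and the test was not matched on signal. H3K4me3 fold changes in Zbtb11KO differed with signal. Random lists matched on signal to the Hox genes had a median of -0.31, and those matched to cytosolic ribosome genes 1.31. The odds ratio therefore does not part a link between the marks from signal.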

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

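The tests of extra copies of the X segment and of NELF enrichment were chosen after the result was seen, while those of ZBTB11 loss in the segment and both tests on H3K27me3 were set before it.

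H3K27me3 domains at the most significant events of each factor differed between the knockouts. Of the 200 most significant ZBTB11 events, 40 lay near a domain in Zbtb11KO and 1 in Zfp131KO (exact McNemar p = 3.82e-11), and of the ZFP131 events 4 and 49 did (exact McNemar p = 6.82e-13). Unbound H3K4me3 domains with like reads gained an H3K27me3 domain in at most 6.60% (upper end of the central 95% of random sets), against 18.8% and 24.9% of those at the events. This comparison does not decide whether active promoters gained more domains in general. Unbound domains with H3K27me3 already in wildtype counted as not gained, and H3K27ac was not matched. H3K27ac fell more often where a domain was gained, with a larger Fisher's exact p of 3.47e-11, which is consistent with a move from an acetylated to a methylated state at Mrpl13, Taco1, Ddx51 and Nup214 when the bound factor is absent. The choice of events after seeing the tables, and whether the change is direct, stay open.

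CHD4 on chromosome X from 92 to 108 Mb differed between the knockouts, by a median of 1.32 on the log2 scale over 15 regions measured in both (permutation p = 0.001, the smallest that 1000 random autosomal windows of the same length can give, with a random maximum of 0.967). CHD4 on the rest of X also had a median of 0.79 in Zbtb11KO against 0.15 in Zfp131KO. Autosomal windows therefore do not show that the segment differs from the rest of X. Loss of ZBTB11 at bound promoters of the segment was argued against, since CHD4 regions with no event of either factor still lay 0.43 above the rest of X. Across the 5 targets other than SIN3A, which set the segment, such regions lay 0.43 to 1.64 above it, so extra copies of the segment in the Zbtb11KO line are a candidate explanation. By listed reads at promoters, the segment was not raised in the double knockout, which also lacks ZBTB11. It differed from the rest of X by -0.14 for H3K4me3 and -0.13 for NELF, against 1.03 and 0.88 in Zbtb11KO. These values argue against loss of ZBTB11 alone as the cause of the higher values, although the double knockout also lacks ZFP131. The labels name no genomic input per genotype, so copy number itself was not measured. Calls at Ogt, Amer1, Rps4x, Nhsl2, Gspt2, Pin4, 8030474K03Rik, Gm4779, Uprt and Phka1 in Zbtb11KO carry this limit.

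NELF was lower at nearly all promoters in every knockout. The share of reads in events fell by 1.24 on the log2 scale from wildtype to Zbtb11KO, and the median region of the authors' deposited table by 1.04, so lower enrichment of the libraries and a loss of NELF at all sites cannot be told apart without an added reference. The SD of log2 ratios among promoters was at least 5.36 times that of simulated counts in both single knockouts, which decides nothing on 1 factor for all sites. The simulation held counting noise but no spread between libraries, and only promoters still listed entered. The cause of the low values of Fgf4 and Sox2 and the high values of p53 targets stays open.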

How the results depend on the processing

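Alternatives named as added were chosen after seeing the data, and the others before. No paired analysis was possible because the files hold no values per region and library, and for the same reason the planned fits with DESeq2, edgeR size factors, total counts, no filter, a replicate number as a term, each replicate left out in turn and all genotypes together were not run, nor was any NELF table alternative in Zfp131KO. Of 369 alternatives for single gene lists 326 kept their side of the threshold and 43 lost it, with no list on the opposite side. The 326 include 64 with centred fold changes, which could not move, since subtracting 1 constant from all promoters leaves the percentile unchanged. Of 65 for bound sites 56 kept theirs, and of 82 counts of changed sites 42 stayed within 1.5 times. Binding overlap and binding at promoters kept theirs in all 9 alternatives. The cause of the shifts below was not tested, except where fewer regions or a stricter threshold make a count smaller by construction.

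With an adjusted p under 0.01, changed sites numbered 16195 for NELF in Zbtb11KO (34660.0 at 0.05), 10224 for H3K4me3 in Zfp131KO, 10822 and 12940.0 for H3K27ac in Zbtb11KO and Zfp131KO, 5764 and 6815 for H3K27me3, 618 and 1322 for CHD4, and 3392 and 1563 for SIN3A. With an absolute log2 fold change of at least 1 as well, they numbered 10180.0 for H3K4me3 in Zfp131KO and 4250.0 and 1724 for SIN3A. Centred on the median of all sites, NELF had 396 calls with 53.8% rises (0.323% before), and H3K4me3 in Zbtb11KO 72.9% rises (62.5% before). Among sites with signal at or above the median they numbered 21435 for NELF, 7996 for H3K4me3 in Zfp131KO, 5974 and 6905 for H3K27ac, 3670.0 and 4788 for H3K27me3, 647 and 1168 for CHD4, and 4473 and 2620.0 for SIN3A.

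Among the added alternatives, counting overlapping regions once left 20442 NELF loci and 4795 SIN3A loci in Zbtb11KO. Regions in the lists of both genotypes gave 18391 for NELF, 7418 for H3K4me3 in Zfp131KO, 2366 and 3316 for H3K27ac, 333 and 966 for H3K27me3, 91 and 147 for CHD4, and 5530.0 for SIN3A in Zbtb11KO. Regions of 500 bp or more gave 6879 for H3K4me3 in Zfp131KO, 2473 and 3420.0 for H3K27ac, and 339 and 1030.0 for H3K27me3. Counts of H3K27ac, H3K27me3 and CHD4 changes therefore rest largely on short regions or regions listed in 1 genotype.

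At sites bound by either factor, random sets from unbound promoter sites turned the side of the median for H3K27ac (-0.11 in Zbtb11KO and -0.12 in Zfp131KO), H3K27me3 (-0.13 and -0.15) and CHD4 (0.0246 and -0.21). H3K4me3 in Zbtb11KO within 1 kb (0.24), CHD4 in Zbtb11KO within 200 bp (0.0298) and H3K27me3 in Zbtb11KO over regions in both lists (-0.18) no longer passed.

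Wildtype NELF events with a knockout event came to 46.7%, 48.9% and 31.0% within 1 kb in Zbtb11KO, Zfp131KO and the double knockout, 29.3%, 32.0% and 16.7% within 200 bp, and 45.1%, 48.6% and 28.1% for the more significant 50% of each list. Wildtype H3K4me3 domains came to 85.1%, 84.3% and 91.8% for the more significant 50% and 53.3%, 56.1% and 66.2% with an overlap of at least 50% of the wildtype domain. Shared changes by Spearman correlation were 0.500 for H3K4me3, 0.697 for H3K27ac, 0.513 for H3K27me3, 0.748 for CHD4 and 0.633 for SIN3A. Pearson correlations were 0.579 for H3K27ac, 0.456 for H3K27me3, 0.737 for CHD4 and 0.664 for SIN3A with signal at or above the median. Over regions in the lists of all 3 genotypes (added) Pearson correlations were 0.391, 0.728, 0.616, 0.493 and 0.627 in the order H3K4me3, H3K27ac, H3K27me3, CHD4 and SIN3A, and without chromosomes X and Y (added) 0.647 for SIN3A. NELF against H3K4me3 gave a Spearman correlation of -0.046 and, with the mean of all sites of a promoter, 0.016.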

Other observations

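Y-linked genes were lower in Zbtb11KO for several targets. Copy number of Y was not measured, and whether these falls belong to the line or to loss of ZBTB11 was not tested. In the same line the HA list, taken with doxycycline, held 5 events on Y and the CHD4 list 1. In the authors' deposited tables NELF at Eif2s3y was -3.50 (SE 0.53, adjusted p = 5.08e-08) and at Ddx3y -6.58 (SE 1.24), and H3K27ac at Uty was -9.74 (SE 1.54). In Zfp131KO the authors' deposited table gave H3K4me3 values of -0.29 (adjusted p = 0.661) for Ddx3y, 0.13 for Eif2s3y and -0.23 for Uty and a rise of 1.21 (adjusted p = 0.0230) for Gm52481, and H3K27ac values of -1.68 (SE 0.51, adjusted p = 0.00657) for Uty and -2.43 (adjusted p = 0.540) for Ddx3y. H3K27ac domains on Y held 611 reads in wildtype, and none were listed in either single knockout. H3K4me3 domains on Y held 1688 reads in wildtype, 190.0 in Zbtb11KO, 1129 in Zfp131KO and 961 in the double knockout, and the NELF lists held 8 events on Y in wildtype and 1 in Zfp131KO, with none in the other lists.

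Listed reads gave the double knockout on the segments. On X from 92 to 108 Mb, H3K4me3 at 73 promoters lay above the rest of X by 1.03 in Zbtb11KO, against -0.17 in Zfp131KO and -0.14 in the double knockout, and NELF by 0.88, -0.05 and -0.13. On chromosome 10 from 58 to 64 Mb, H3K4me3 at 54 promoters lay above the rest by 0.62, 0.50 and 0.56.

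NELF events remained near 84.5% of the 200 most significant ZBTB11 events in Zbtb11KO, 94.5% in Zfp131KO and 55.0% in the double knockout, and near 96.5%, 88.5% and 70.5% of the ZFP131 events.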
